A study of Mus musculus with 8 samples.

How the data were processed

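RNA was sequenced from mouse Th1 cells, T helper cells that make interferon gamma, grown from C57BL/6 CD4 T cells activated through CD3 and CD28 with IL-12 at 2 ng/ml and an antibody against IL-4 at 5 µg/ml. The 8 libraries fall into 4 groups of 2. A knockdown experiment set a short hairpin RNA against Pcbp1 beside a scrambled hairpin and sequenced total RNA depleted of ribosomal RNA. A second experiment set CPX (ciclopirox olamine), an iron chelator, beside its solvent DMSO and, per the labels, used polyA RNA. The CPX dose, the hours of treatment, the time after transduction and the sequencing dates are not given in the sources used here. The labels number the replicates but do not say whether they came from separate cultures or animals.

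The submitters' processing notes name cutadapt, STAR, HTSeq and DESeq with the mouse genome build mm9, without versions, annotation or filters. The deposited per-library table is named RPM (each gene's share of a library's reads times 1e+06), and the design fixed before the data were examined assumed that unit, but its values are not RPM. For the knockdown experiment the deposited values are raw counts per gene, since dividing them by 1 size factor per library gives the authors' mean normalized counts within a relative tolerance of 2e-09. For the CPX experiment the deposited values behave as a score, counts multiplied by 1 factor common to the 4 libraries (1.98 reads per unit) and rounded to whole numbers, so the whole reads could not be recovered. The authors' result tables hold a mean signal (the mean of the counts after division by the size factors), log2 fold changes with standard errors on the log2 scale, a Wald statistic given as a score, and p-values with adjusted p-values, all from DESeq2 per the file headers. These tables were used to find gene names and for comparison.

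The labels of the per-library table were displaced. The table lists 33899 genes, and 1 line, labelled Ins1, holds the constant 23487630 in every library. Lines with a value of at least 10 in 1 library, 14805 in all, were assigned to the gene whose mean signals in both of the authors' tables they gave (relative tolerance 2e-09 in the knockdown, absolute tolerance 1.2 in the CPX table). Of these, 14455 matched exactly 1 gene, 350 matched more than 1 and were left out, and 0 matched none. All 7208 matched lines before the constant line carried their own gene's label. After it, 7246 of 7247 carried another gene's. The median absolute difference between fitted and listed CPX means was 0.212 and the 99th percentile was 0.773. Dates or numbers stood in place of 25 gene names in the authors' files.

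RPM was computed here as a value divided by its library's total (without the constant line) times 1e+06. Genes with at least 1 RPM in at least 2 of the 4 libraries of an experiment were tested. The knockdown was tested on counts with edgeR 4.0.16 (quasi-likelihood test, TMM scaling). CPX was tested with limma 3.58.1 (trended variance) on log2(RPM + 0.5), and so was the difference between the effects, with the contrast of knockdown minus CPX effect over all 8 libraries. R was version 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) are those of the log2 fold change, taken from the limma fit for CPX. For the knockdown the SE was worked back, as the size of the log2 fold change over the square root of edgeR's F statistic. The SEs of the 2 experiments are therefore not the same quantity. Standard deviations (SD) are over the 2 libraries of a group. Group means of RPM carry no TMM scaling, so their ratio can depart from the knockdown fold change. The totals include the mitochondrial ribosomal RNA mt-Rnr2, the top gene of the knockdown experiment. It held 17.6% of each scrambled total and 19.9% and 19.3% of the Pcbp1 hairpin totals. RPM from these totals, without TMM scaling, also entered the test of the difference.

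Before the data were examined, 40 gene lists were fixed: 32 of functions or lineages and 8 of markers of other cells (cytotoxic and NK, CD8 T, B, macrophage and monocyte, dendritic, neutrophil, erythroid, and fibroblast or packaging cells). The 35 lists with at least 5 tested members in a comparison were tested with camera, with an inter-gene correlation of 0.01 and, beside it, an estimated correlation, and adjusted over the lists. Members were also adjusted over the list alone. The named genes follow a rule set at the same time. It takes 12 genes chosen in advance and the 8 largest rises and falls among called genes whose groups do not overlap and whose higher group averages at least 5 RPM. It adds up to 4 members with the smallest p of each list that was called or held at least 3 called genes, and at most 1 member of any other list. For the difference and for genes called in both comparisons it takes 5 per direction. A further 5 lists (heat shock proteins, purine and pyrimidine synthesis, tRNA synthetases, proteasome subunits, lysosomal genes) were chosen after the result was seen.

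Alternatives set in advance were pseudocounts of 0.1 and 2, no filter, a filter of 5 RPM, median ratio scaling, quantile normalization, an untrended variance, 1 fit of all 8 libraries, a replicate block, DESeq2 1.42.0 or limma in place of the test used, and leaving out each library. For the knockdown, the pseudocounts, quantile normalization and the fit of all 8 libraries used limma without TMM scaling in place of edgeR. Added after the data were seen were edgeR and DESeq2 on the deposited whole numbers of the CPX experiment, the lines whose own label matched, and a correction for GC content and transcript length. The correction took a spline (5 degrees of freedom for each of GC content and log length) out of each library's deviation from the gene mean. Reference transcripts were found for 14005 of the 14455 genes (96.9%), 1228 of them through older symbols. Centring the correction in each library was decided after its first output, and both forms are reported.

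Totals per library were 14174293 and 14321096 reads for scrambled hairpin, 15518303 and 14299941 for Pcbp1 hairpin, and in deposited units 19662145 and 19547221 for DMSO and 19193784 and 19239061 for CPX. Simulated data took these depths, 1 dispersion common to all genes of an experiment, and few changed genes (66 or 67 per fold and the list below). In the knockdown design edgeR recovered 67.2% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold. It made 3 false calls among the unchanged ones of 11575 genes. In the CPX design limma recovered 0%, 7.46% and 84.8%, with 3 false calls among the unchanged ones of 11466 genes. The real genes differ in spread and far more of them were called, so these shares are not the power of the real tests. Camera called a simulated list of 30 genes changed 2-fold in both designs. With 2 libraries per group no test for outlying libraries was made.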

Results

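The transcriptomes of mouse Th1 cells were measured by RNA sequencing after 2 perturbations, with 2 libraries in each of 4 groups. In the first experiment the cells carried a short hairpin RNA against Pcbp1, which encodes an RNA-binding protein that also delivers iron to ferritin, or a scrambled hairpin. In the second they were treated with CPX, a chelator of intracellular iron, or with its solvent DMSO. The question was which transcripts change with the Pcbp1 hairpin and with CPX. Neither PCBP1 protein nor cellular iron was measured in the data used here. The knockdown libraries held 14174293 to 15518303 reads assigned to genes. The CPX experiment's libraries held 19193784 to 19662145 units of its rescaled table, each standing for 1.98 reads. Replicates correlated across genes at 0.993 for scrambled hairpin, 0.993 for Pcbp1 hairpin, 0.980 for DMSO and 0.954 for CPX (Pearson, log2 scale). Between the 2 CPX replicates 1538 genes differed by more than 2-fold, and between the DMSO replicates 481 did, against 47 and 45 in the scrambled and Pcbp1 hairpin groups. The experiments differed in RNA selection (total RNA without ribosomal RNA, and polyA RNA). Levels are therefore compared within an experiment only, apart from a correlation of group means given at the end with the length trend. The labels do not say that replicates came from separate cultures or animals, so every p-value measures only the spread between these samples, technical or not.

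Pcbp1 itself stood at 44.0 and 51.7 RPM in the scrambled libraries and at 15.1 and 16.1 RPM in the Pcbp1 hairpin libraries, 3.31-fold lower (log2 fold change -1.73, SE 0.12, edgeR's quasi-likelihood test, adjusted p = 3.18e-05). It stood at 506 and 538 RPM with DMSO and at 238 and 199 RPM with CPX, so the chelator also lowered Pcbp1 mRNA, by 2.40-fold (-1.26, SE 0.20, limma, adjusted p = 0.00613). Pcbp2, its closest paralog, rose slightly after the knockdown (50.7 and 49.2 RPM against 65.1 and 64.6 RPM; 0.27, edgeR, adjusted p = 0.0152), a call that was lost without scrambled replicate 2 (0.0794) or Pcbp1 hairpin replicate 2 (0.0732) and with DESeq2 (0.0929). With CPX the Pcbp2 value was 0.52 (adjusted p = 0.0673, and 0.0394 without CPX replicate 1).

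**Figure D1:**
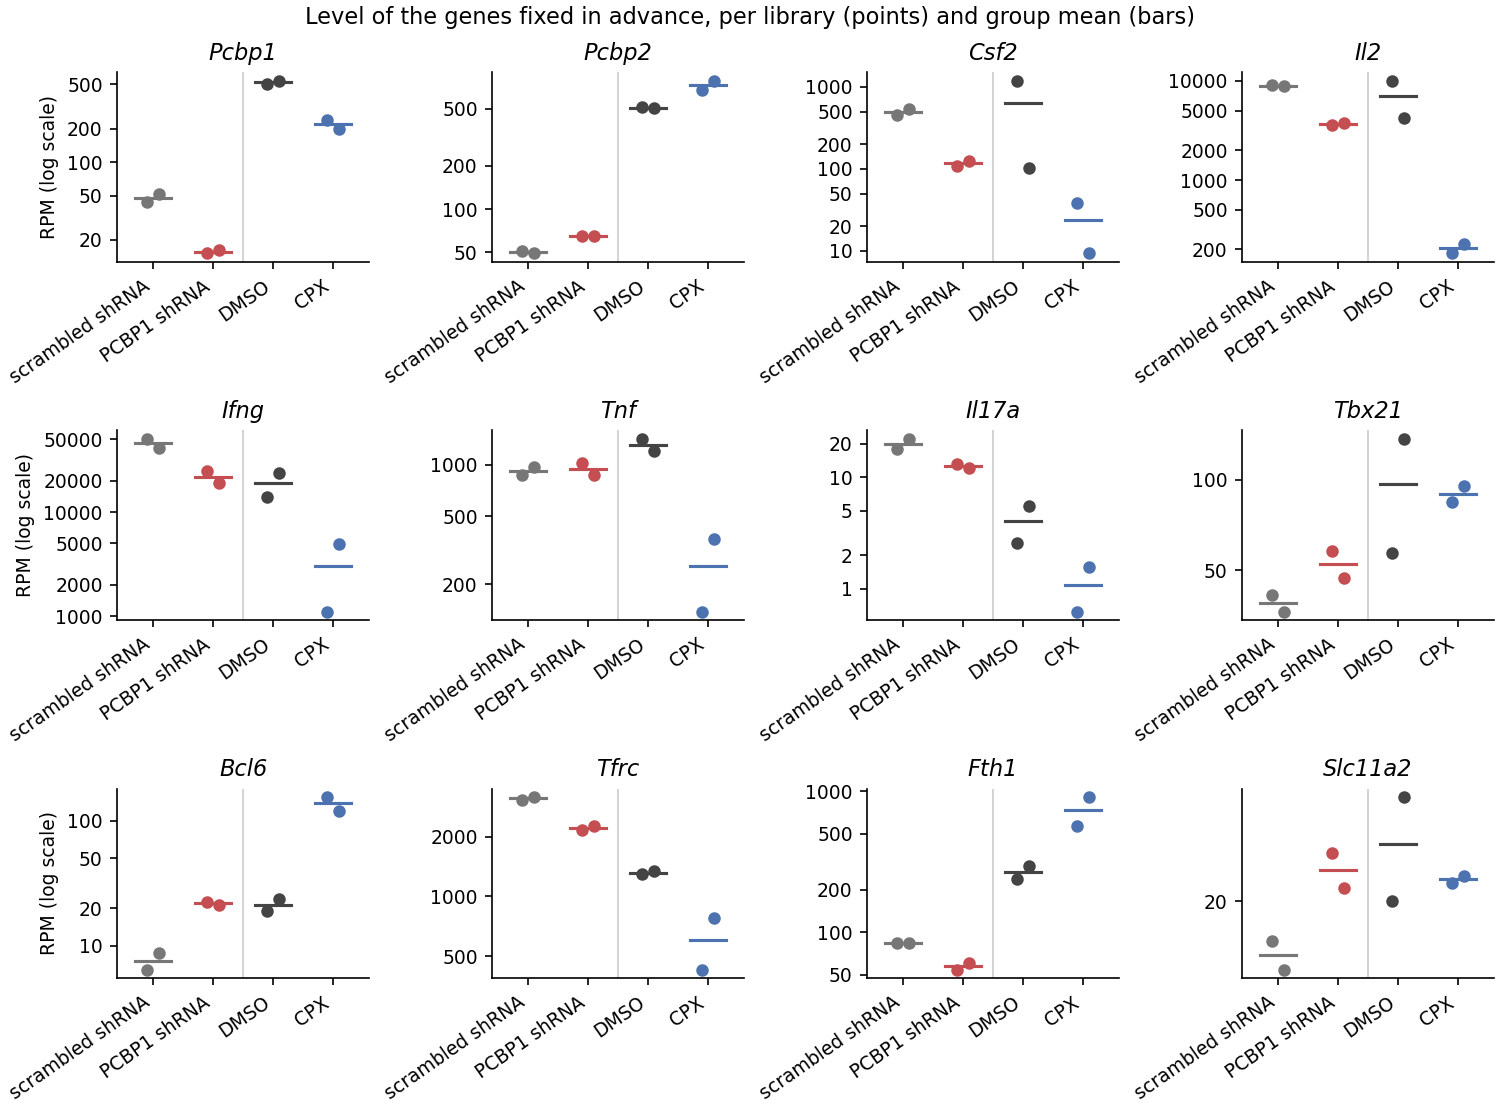
Level in RPM (log axis) of the 12 genes chosen in advance, in each library (points) with the group mean (bars), n = 2 per group, the grey line parting the 2 experiments. Csf2, Il2, Ifng and Pcbp1 were lower in both perturbed groups than in their controls, while Fth1 fell after knockdown and rose with CPX.

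After the knockdown of Pcbp1, Csf2, Il4, Il2, Ifng and Il21 fell in these Th1 cells. Csf2, which encodes the cytokine GM-CSF, fell 4.55-fold, from 459 and 534 RPM in the scrambled libraries to 109 and 127 RPM (log2 -2.19, SE 0.11, edgeR's quasi-likelihood test, adjusted p = 1.27e-05). Il4, the signature cytokine of Th2 cells, fell 6.61-fold from 64.9 ± 9.16 to 10.6 ± 1.57 RPM (SD, n = 2 each), and Il2, the T cell growth factor, fell 2.64-fold from 8952 ± 87.7 to 3653 ± 138 RPM. Ifng, the signature cytokine of Th1 cells, fell 2.25-fold from 45668 ± 6668 to 21904 ± 4121 RPM (adjusted p = 8.25e-04). Il21, a helper cytokine for B cells, fell from 258 ± 19.5 to 79.1 ± 4.95 RPM. Tnf did not pass (922 ± 69.1 and 949 ± 114 RPM, adjusted p = 0.602). In the other direction, Nolc1 and Rrs1, both needed to build ribosomes, rose 7.47-fold (54.3 ± 0.697 to 436 ± 23.2 RPM) and 7.30-fold. Hnrnpm, a splicing regulator, rose 5.28-fold (56.5 ± 1.42 to 321 ± 3.09 RPM), and Bcl6, a repressor of transcription that drives follicular helper T cells, rose 2.67-fold (7.57 ± 1.63 to 21.8 ± 1.01 RPM).

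Across the genome edgeR called 6482 of 11575 genes (56.0%) after the knockdown, 3396 that rose and 3086 that fell, with 1089 and 502 of them changed at least 2-fold. The median log2 fold change was 0.00. The split depends on the processing: 3080.0 rose and 3440.0 fell with limma after quantile normalization, and 4003 and 2502 with limma alone. With length and GC content taken out without centring, 2115 rose and 3839 fell. The groups did not overlap for 78.5% of genes, where chance gives 33.3%. The authors' deposited table calls 4987 of 11443 genes, and 4969 genes were called in both, all in the same direction. In 1 limma fit of all 8 libraries, with 1 shared estimate of the spread and no TMM scaling, 2759 genes were called, 1971 that rose and 788 that fell. Csf2 (limma, adjusted p = 0.200), Ifng (0.263), Fth1 (0.116) and Tfrc (0.199) no longer passed in that fit. Limma on the knockdown libraries alone, also without TMM scaling, called 6505 genes. Both limma fits had a median log2 fold change of 0.10, so that shift came without the shared spread.

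The largest rises after the knockdown, as log2 fold changes, were in Cd9 (3.55), a tetraspanin of the cell surface, Gopc (2.94), a Golgi protein, Nolc1 (2.90), Rrs1 (2.87), Rps16-ps2 (2.75), Clptm1 (2.61), Srm (2.58), which encodes spermidine synthase, and Sdha (2.57), a subunit of succinate dehydrogenase. Rps16-ps2 is a processed pseudogene whose reads cannot be parted with certainty from its parent gene. The largest falls were in Il4 (-2.73), Csf2 (-2.19), Serpinb5 (-2.18), Il31 (-2.18), Cd160 (-2.14), an inhibitory receptor, Timp2 (-2.05), Areg (-2.01), a ligand of the EGF receptor, and Ccr8 (-2.00), a chemokine receptor of Th2 cells. In 1 fit of all 8 libraries 57 of the genes named for the knockdown lost their call. Among these largest falls they were Csf2 (adjusted p = 0.200), Serpinb5 (0.462), Il31 (0.115), Cd160 (0.0504), Timp2 (0.185) and Ccr8 (0.0508).

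Of 24 measured T cell cytokine genes, 17 fell and 2 rose (17 and 2 adjusted over the list alone), with a median log2 fold change of -1.14 (camera, adjusted p = 3.14e-05). None of the list calls for the knockdown held with an estimated correlation (camera, adjusted p = 0.541 for the cytokines). With 2 libraries per group that form of camera has few degrees of freedom and little power. Its lowest unadjusted p was 0.0372 over the knockdown lists and 0.0575 over the CPX lists. A call lost with it, here and below, cannot tell an absent shift from a weak test. The cytokines that fell included Il21 (-1.81) and Tnfsf11 (-1.14). Of 10 Th2 genes, 6 fell and 1 rose (6 and 1 adjusted over the list alone), among them Il13 (-1.16) and Ccr4 (-1.27), median -1.22 (camera, adjusted p = 0.0465; adjusted p = 0.541 with an estimated correlation), a call lost with replicates paired by number (0.0542), a filter of 5 RPM (0.0772), median ratio scaling (0.0581), quantile normalization (0.0704) and 1 fit of all 8 libraries (0.127). Among 19 Th1 genes 4 rose and 5 fell (3 and 5 adjusted over the list alone). Nkg7, a protein of cytotoxic granules, rose by 2.25, Il18rap fell by 1.62 and Fasl fell by 0.81, and the list was not called (median 0.13, mean -0.07, camera direction down, adjusted p = 0.689). Tbx21, the master regulator of Th1 cells, rose by 0.33 (adjusted p = 0.0485), a call lost without scrambled replicate 2 (0.192), without Pcbp1 hairpin replicate 1 (0.239) and with DESeq2 (0.0824). Without scrambled replicate 1, 2 Th1 genes rose, and without Pcbp1 hairpin replicate 1, 8 fell.

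Other T cell lists did not pass the list test. With replicates of the same number paired, regulatory T cell genes (camera, adjusted p = 0.0310) and early T cell receptor response genes (0.0382) passed, each at adjusted p = 0.679 with an estimated correlation. Of 8 chemokines 6 fell, Ccl1 at -1.28 and Cxcl2 at -1.04, and 1 rose, Ccl5 at 1.59 (6 and 1 adjusted over the list alone; median -0.79, camera, adjusted p = 0.0632). Of 10 regulatory T cell genes 5 fell and 0 rose, including Il10 (-1.42), Tnfrsf18 (-1.38) and Ctla4 (-1.25), with 5 also adjusted over the list alone (median -0.50, camera, adjusted p = 0.0605). Of 11 Th17 genes 6 fell and 3 rose, with Batf at -1.05, Il1r1 at 1.08 and Il17a at -0.77 (6 and 3 adjusted over the list alone; median -0.65, camera, adjusted p = 0.298). Of 15 naive and memory genes 8 rose and 4 fell (8 and 4 adjusted over the list alone), Foxo1 by 1.35 and Bach2 by 1.12 among the rises (median 0.50, camera, adjusted p = 0.319). Of 26 early T cell receptor response genes 12 rose and 2 fell (12 and 2 adjusted over the list alone), with Nfatc1 at 1.25, Nfkb1 at 1.10 and Cd69 at -1.47 (median 0.30, camera, adjusted p = 0.0866). Of 10 coinhibitory receptors 3 rose, Lag3 by 0.90 among them, and 5 fell, Btla at -0.82 (3 and 5 adjusted over the list alone; median -0.16, camera, adjusted p = 0.451). Of 21 interferon-stimulated genes 8 fell, with Gbp2 at -1.41 and Zbp1 at -1.05, and 1 rose (8 and 0 adjusted over the list alone; median -0.29, camera, adjusted p = 0.0934). Whichever library was left out, 1 or 2 coinhibitory receptors rose.

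Most ribosome biogenesis genes rose after the knockdown and most ribosomal protein genes fell, though the difference between the lists was not tested. Both medians shrank with length and GC content taken out, to 0.28 and -0.26. Of 28 ribosome biogenesis genes 19 rose and 7 fell (19 and 7 adjusted over the list alone), with Mybbp1a at 1.69, Pes1 at 1.68 and Bysl at 1.65 (median 0.52, camera, adjusted p = 0.00813; adjusted p = 0.541 with an estimated correlation). Of 46 cytosolic ribosomal protein genes 33 fell and 4 rose (33 and 4 adjusted over the list alone), with Rpl7 at -1.06, Rps4x at -1.02 and Rps14 at -0.98 (median -0.54, camera, adjusted p = 7.41e-06; adjusted p = 0.541 with an estimated correlation). Of 23 genes of PCBP and hnRNP proteins, a family of RNA-binding proteins that act in splicing and mRNA stability, 18 rose and 2 fell, 1 of these Pcbp1 (18 and 3 adjusted over the list alone), with Hnrnpm at 2.40, Hnrnph2 at 2.37, Ptbp1 at 1.58 and Hnrnpab at 1.55 (median 0.98, camera, adjusted p = 4.41e-05; adjusted p = 0.541 with an estimated correlation). Of 24 regulators of cytokine mRNA stability 13 rose and 6 fell (13 and 6 adjusted over the list alone), Zfp36l2 at 1.62 and Khsrp at 1.11, and the list was not called (median 0.25, camera, adjusted p = 0.0772).

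Most histone genes fell after the knockdown. Mitosis genes were called down as a list, although 14 of 28 members did not pass. Of 21 replication-dependent histone genes 17 fell and 0 rose (19 and 0 adjusted over the list alone), with Hist2h4 at -1.49 and Hist1h1c at -1.41 (median -1.05, camera, adjusted p = 7.41e-06; adjusted p = 0.663 with an estimated correlation). Of 28 mitosis genes 13 fell and 1 rose (13 and 1 adjusted over the list alone), Cdk1 at -1.11 and Cenpa at -0.78, with Plk1 at 1.63 as the rise (median -0.65, camera, adjusted p = 0.00816; adjusted p = 0.826 with an estimated correlation). The mitosis call was lost without scrambled replicate 1 (adjusted p = 0.0610) and without Pcbp1 hairpin replicate 2 (adjusted p = 0.168). Of 32 DNA replication genes 17 fell and 6 rose (17 and 7 adjusted over the list alone), Mcm4 at 0.96 (median -0.34, camera, adjusted p = 0.0934). Of 25 p53 target genes 11 rose and 8 fell (11 and 8 adjusted over the list alone), Plk3 at 1.36 and Fas at -0.82 (median 0.31, camera, adjusted p = 0.711). Of 24 apoptosis regulators 12 fell and 5 rose (12 and 5 adjusted over the list alone), Bcl2a1b at -0.94 and Bcl2l11 at 0.86 (median -0.36, camera, adjusted p = 0.0465; adjusted p = 0.568 with an estimated correlation). The apoptosis call was lost without Pcbp1 hairpin replicate 2 (adjusted p = 0.0638) and with median ratio scaling (0.0581), no trend of the spread (0.0585), quantile normalization (0.0704), a filter of 5 RPM (0.0732) or 1 fit of all 8 libraries (0.127). Without scrambled replicate 1, 6 mitosis genes and 5 p53 target genes fell, and without Pcbp1 hairpin replicate 1, 22 mitosis genes fell. Without scrambled replicate 2 or Pcbp1 hairpin replicate 2, 5 p53 target genes fell.

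Iron genes shifted in both directions after the knockdown. Tfrc, the transferrin receptor, fell from 3114 ± 62.0 to 2213 ± 58.2 RPM (SD, n = 2 each; -0.60, edgeR, adjusted p = 7.37e-04), and Fth1, the ferritin heavy chain, fell from 84.2 ± 0.0817 to 57.2 ± 4.11 RPM (-0.66). Quantile normalization, fitted with limma in place of edgeR, ended the Tfrc call (-0.16, adjusted p = 0.125) and the Ifng call (-0.23, adjusted p = 0.271). Hmox1, the heme oxygenase, rose by 1.65 and Aco1, the iron regulatory protein, by 1.25. Slc11a2, an iron importer, rose by 0.39 (adjusted p = 0.0260), a call lost without scrambled replicate 2 (0.129), without Pcbp1 hairpin replicate 1 (0.141) and with DESeq2 (0.107). Of 17 iron handling genes 6 rose and 7 fell (6 and 7 adjusted over the list alone; median -0.22, camera, adjusted p = 0.457). Of 28 iron-dependent dioxygenases 18 rose and 3 fell (18 and 3 adjusted over the list alone), the RNA demethylase Fto at 1.64, Hif1an at 1.54 and Tet3 at 1.39 (median 0.50, camera, adjusted p = 0.00522; adjusted p = 0.541 with an estimated correlation). With length and GC content taken out, 12 rose and 6 fell and the call was lost (median 0.13, adjusted p = 0.220). Of 21 iron-sulfur cluster assembly genes 8 rose and 8 fell (8 and 9 adjusted over the list alone), Isca1 at 1.65 and Glrx5 at 1.35 (median 0.07, camera direction down, adjusted p = 0.926). Of 13 heme synthesis genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), Slc25a38 at -0.76 (median -0.02, mean 0.03, camera direction up, adjusted p = 0.926). Without scrambled replicate 2, 3 iron handling genes rose, and without Pcbp1 hairpin replicate 1, 5 dioxygenases fell. Of the heme synthesis genes 1 rose without scrambled replicate 1, and 1 fell without either Pcbp1 hairpin library.

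Among metabolic and stress lists, 9 of 18 glycolysis enzymes rose and 1 fell (9 and 1 adjusted over the list alone), Gpi1 at 2.07, Hk2 at 1.38 and Pfkp at 1.18 (median 0.40, camera, adjusted p = 0.0423; adjusted p = 0.541 with an estimated correlation). The glycolysis call was lost with no trend of the spread (adjusted p = 0.0585), 1 fit of all 8 libraries (0.151) and length and GC content taken out (0.0560). Of 35 nuclear respiratory chain genes 20 fell and 6 rose (21 and 6 adjusted over the list alone), Ndufb5 at -0.97 and Cox7a2 at -0.87 (median -0.34, camera, adjusted p = 0.0116; adjusted p = 0.663 with an estimated correlation). With length and GC content taken out, 11 fell and 8 rose and the call was lost (median -0.09, adjusted p = 0.808). The lists that follow were not called by camera. Of 30 HIF target genes 13 rose and 6 fell (13 and 6 adjusted over the list alone), Bhlhe40 at 1.97 (median 0.34, adjusted p = 0.140). Of 21 TCA cycle enzymes 9 rose and 9 fell (9 and 10 adjusted over the list alone), Ogdh at 1.52 and Mdh2 at 1.36 (median -0.14, mean 0.21, camera direction up, adjusted p = 0.926). Of 8 mitochondrially encoded genes 4 rose and 1 fell (4 and 2 adjusted over the list alone), mt-Nd2 at 0.82 (median 0.17, adjusted p = 0.499). Of 19 cholesterol synthesis genes 7 rose and 1 fell (7 and 0 adjusted over the list alone), Nsdhl at 2.02 (median 0.20, adjusted p = 0.140). Of 24 ATF4 target genes 5 rose and 7 fell (5 and 7 adjusted over the list alone), Slc7a5 at 1.12 and Psph at -1.27 (median -0.22, adjusted p = 0.466). Of 19 unfolded protein response genes 6 rose and 7 fell (7 and 7 adjusted over the list alone), Pdia6 at 0.90 and Dnajc3 at -0.82 (median -0.02, mean 0.00451, camera direction up, adjusted p = 0.888). Of 15 NRF2 genes 5 rose and 2 fell (5 and 2 adjusted over the list alone), Sod1 at -1.11 and Sod2 at 0.95 (median 0.17, adjusted p = 0.607). Without scrambled replicate 1, 3 ATF4 targets and 2 mitochondrially encoded genes rose. Without Pcbp1 hairpin replicate 1, 11 ATF4 targets fell and 8 NRF2 genes rose, and without Pcbp1 hairpin replicate 2, 8 ATF4 targets and 3 respiratory chain genes rose.

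Most markers of other cells were sparse in the knockdown libraries, but Cd8a was not in replicate 1. Cd8a stood at 63.8 and 67.1 RPM in replicate 1 of the scrambled and Pcbp1 hairpin groups and at 6.49 and 6.92 RPM in replicate 2, so it differed between replicates and not between groups. Across genes, the differences between replicates correlated at 0.307 between the scrambled and Pcbp1 hairpin groups (Pearson). Libraries of the same number thus shared part of their deviation, and the main fit did not pair them. Of 5 CD8 T cell markers and 5 cytotoxic and NK cell genes 0 passed, also adjusted over the list alone, with Cd8b1 at -0.22 (0.828) and Gzma at -0.63 (0.269), and camera called neither list (adjusted p = 0.888 and 0.532). With replicates of the same number paired, edgeR called Gzma (-0.64, adjusted p = 2.23e-06), Thy1 (0.0119) and Ebf1 (0.0266). Gzma was also called without scrambled replicate 2 (-1.13, adjusted p = 0.0197) and without Pcbp1 hairpin replicate 1 (-1.40, adjusted p = 0.00948), as were Thy1 without Pcbp1 hairpin replicate 1 (0.00909) and Ebf1 without Pcbp1 hairpin replicate 2 (0.0303). Cd8b1 was called without Pcbp1 hairpin replicate 1 (-1.87, adjusted p = 0.0472). Of 5 dendritic cell markers 3 fell, Xcr1 at -0.68 among them (3 adjusted over the list alone; camera, adjusted p = 0.146). The other calls, Cd74 and Zbtb46, were not stable. Cd74 was lost without either scrambled library (adjusted p = 0.112 and 0.159), without either Pcbp1 hairpin library (0.109 and 0.153) and with DESeq2 (0.202), and Zbtb46 likewise (0.174, 0.0859, 0.127, 0.152 and 0.232). Of the marker lists too short to test, 1 of 2 macrophage and monocyte markers fell (Ccr2, -0.58), 0 of 2 B cell markers passed (Ebf1 0.88, adjusted p = 0.0606), 0 of 3 fibroblast or packaging cell markers (Thy1 -0.19), 0 of 1 erythroid marker (Car2 0.08), and 0 neutrophil markers were measured. Of the cytotoxic and NK cell genes 4 fell without scrambled replicate 2 and 2 without Pcbp1 hairpin replicate 1.

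Fold changes after the knockdown rose with transcript length, from a median of -0.50 over the 1131 shortest to 0.37 over the 1130 longest transcripts (Spearman rho 0.358 across genes, which are not independent replicates), against a rho of 0.0584 for CPX. With the dependence on length and GC content taken out, edgeR called 5436 genes. Cytokines, Th2 genes, histones, mitosis genes, ribosomal proteins, ribosome biogenesis and hnRNP proteins stayed called, with smaller medians for cytokines (-1.14 to -0.59), ribosomal proteins (-0.54 to -0.26, 20 that fell and 7 that rose) and ribosome biogenesis (0.52 to 0.28). By camera they stood at adjusted p from 3.27e-06 to 0.0194 (adjusted p = 0.569 to 0.862 with an estimated correlation). Calls were gained for mitochondrially encoded genes, regulatory T cell genes and DNA replication. Of 8 mitochondrially encoded genes 6 rose and 0 fell after the correction (camera, adjusted p = 0.00107; adjusted p = 0.813 with an estimated correlation). Their median went from 0.169 to 1.198, so most of that shift was put in by the correction. Their median GC content was 37.4%, and whether the correction suits such transcripts was not tested. This call therefore cannot tell a rise of these genes from an effect of the correction. Regulatory T cell genes stood at adjusted p = 0.0274 (camera; adjusted p = 0.569 with an estimated correlation; median -0.496 to -0.583). DNA replication stood at 0.0300 (adjusted p = 0.827 with an estimated correlation; median -0.344 to -0.271). Calls were lost for glycolysis (median 0.40 to 0.21, adjusted p = 0.0560), the respiratory chain (-0.34 to -0.09, 0.808), dioxygenases (0.50 to 0.13, 0.220), Il17a (0.540), Tbx21 (0.340) and Slc11a2 (0.640). The apoptosis list also lost its call (0.0735) but kept most of its size (median -0.36 to -0.31, with 12 members that fell before and after).

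**Figure D2:**
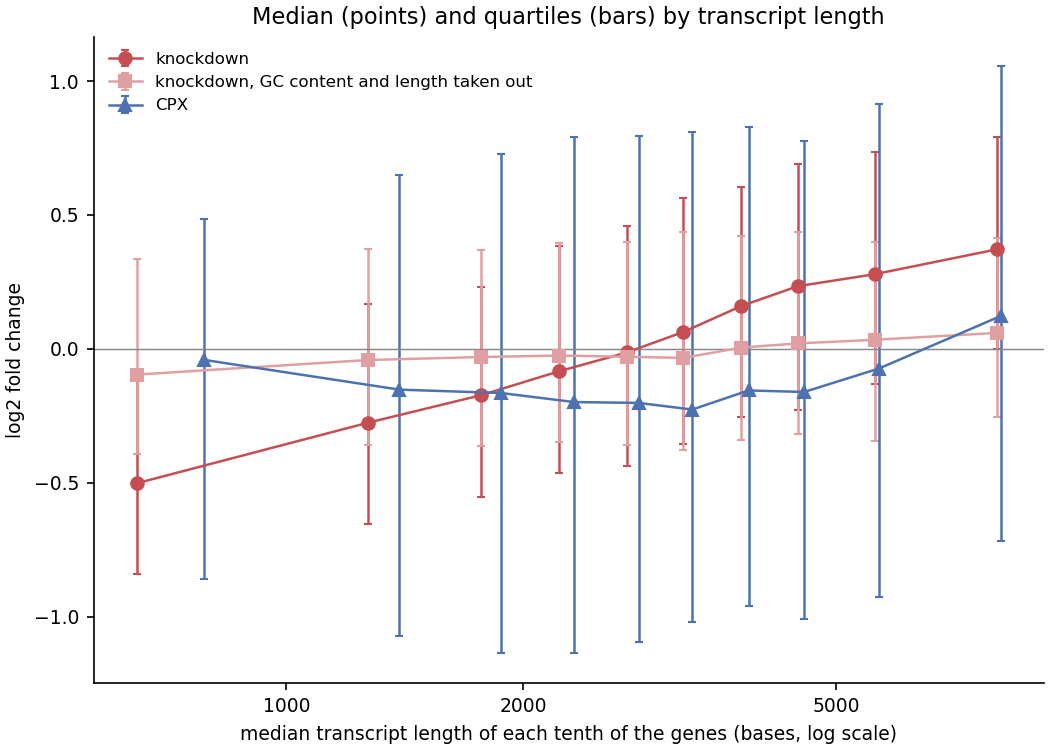
Median log2 fold change (points) and quartiles (bars) in 10 bins of the genes by transcript length (bases, log axis), for the knockdown, for the knockdown with GC content and length taken out, and for CPX. The knockdown medians climb from -0.50 to 0.37, and after the correction they run from -0.10 to 0.06.

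With CPX, Hmox1 and Hspa1a rose, and Il2 and Myc fell. Hmox1, the heme oxygenase, rose 65.3-fold from 28.9 ± 5.72 to 1938 ± 530.5 RPM (SD, n = 2 each; log2 6.03, SE 0.28, limma, adjusted p = 0.00241). The heat shock genes Hspa1a and Hspa1b, a nearly identical pair whose reads cannot be parted with certainty, stood at 3.77 and 5.82 RPM with DMSO and at 9047 and 10840.0 RPM with CPX (10.73 and 10.50). Il2 fell 31.8-fold from 7103 ± 4129 to 204 ± 31.0 RPM, and Myc, a driver of cell growth, fell 27.4-fold from 1408 ± 204 to 51.0 ± 8.40 RPM. Ferritin mRNAs rose, Ftl1 by 1.75 and Fth1 from 266 ± 38.5 to 737 ± 240.4 RPM (1.44, adjusted p = 0.0117), and Tfrc fell from 1320.0 ± 24.9 to 603 ± 248 RPM (-1.19, adjusted p = 0.0275), a call lost without DMSO replicate 1 (0.0643) or 2 (0.0665).

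In all, limma called 5124 of 11466 genes (44.7%) with CPX, 2280 that rose and 2844 that fell, with 2066 and 2535 of them changed at least 2-fold. The median log2 fold change was -0.12, and median ratio scaling moved it to 0.03 and turned the split, with 2635 genes that rose and 2521 that fell. On the deposited whole numbers edgeR called 2573 up and 2467 down, and DESeq2 2814 and 2587. The groups did not overlap for 76.3% of genes, where chance gives 33.3%. The authors' deposited table calls 6524 of 15791 genes, and 4915 genes were called in both, all in the same direction. The count dropped to 2535 without DMSO replicate 1 and to 2785 without DMSO replicate 2, and the share of calls that rose was 56.0% without DMSO replicate 2 and 32.1% without CPX replicate 2, against 44.5% with all 4 libraries.

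Besides Hspa1a, Hspa1b and Hmox1, the largest rises with CPX were in P2rx7 (8.24), an ATP-gated ion channel, Elmod3 (7.27), Efnb2 (6.86), an ephrin ligand, Hey1 (6.10), a Notch target, and Efr3b (6.08). Hey1 was at 0 and 0.102 RPM with DMSO and at 70.1 and 19.6 RPM with CPX. The largest falls were in the chemokine genes Ccl1 (-7.37) and Xcl1 (-5.53), Il1a (-5.75), Slfn2 (-5.53), Serpinb9 (-5.22), which encodes an inhibitor of granzyme B, Il2 (-4.99), Il24 (-4.95) and Polr1b (-4.91), the second subunit of RNA polymerase I. Serpinb9 fell from 504 ± 5.05 to 13.2 ± 2.08 RPM.

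T cell cytokine genes were called down as a list with CPX, although 10 of 23 members did not pass. Of 23 measured T cell cytokines 13 fell and 0 rose (16 and 0 adjusted over the list alone), with Il17f at -4.75, Tnfsf8 at -3.13 and Il22 at -2.70 (median -2.70, camera, adjusted p = 0.00143; adjusted p = 0.757 with an estimated correlation). Ifng fell from 18915 ± 6914 to 3045 ± 2742 RPM (-2.96, adjusted p = 0.0213), and without CPX replicate 1 its adjusted p was 0.0617. Tnf fell by 2.52. The DMSO replicates differed in activation-dependent cytokines: Csf2 stood at 1186 and 104 RPM, Il2 at 10023 and 4183 RPM and Ccl1 at 1123 and 121 RPM. Csf2, at 38.5 and 9.36 RPM with CPX, fell by 4.17 (SE 1.22, adjusted p = 0.0387), a call lost without CPX replicate 1 (0.0598) or 2 (0.162) and with quantile normalization (0.0560). Il17a fell by 1.51 (0.0493), a call lost without DMSO replicate 2 (0.225) or CPX replicate 1 (0.166) and with either other pseudocount (0.0531 and 0.0536). Il3 at -4.20, named after its values were seen, did not pass (0.0514). Of 9 chemokines 7 fell and 0 rose (8 and 1 adjusted over the list alone), Ccl9 at -4.42 and Ccl3 at -2.59 (median -2.59, camera, adjusted p = 0.0132; adjusted p = 0.757 with an estimated correlation). Without CPX replicate 2 the cytokine and chemokine list calls were lost (adjusted p = 0.0639 and 0.0681).

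T cell lineage lists were not called by camera with CPX. With replicates of the same number paired, Th1 genes (adjusted p = 0.0390) and Th2 genes (0.0252) were called, each at adjusted p = 0.708 with an estimated correlation. Of 21 Th1 genes 9 fell and 1 rose (9 and 1 adjusted over the list alone), with the chemokine receptor Cxcr3 at -2.47, Gzmb at -2.44 and Havcr2 at -1.71 (median -1.26, adjusted p = 0.140), while Tbx21 was at 0.02 (0.968). Of 9 Th2 genes 4 fell and 0 rose (4 and 0 adjusted over the list alone), Il13 at -4.65 and Ccr4 at -2.32 (median -2.03, adjusted p = 0.0943). Of 10 Th17 genes 5 fell and 2 rose (5 and 2 adjusted over the list alone), Batf at -3.08 and Rora at 3.42 (median -1.43, adjusted p = 0.276). Of 12 regulatory T cell genes 2 fell and 1, Itgae at 3.15, rose (1 and 1 adjusted over the list alone; median -0.20, adjusted p = 0.640). The falls, Nrp1 and Tnfrsf18, were lost without CPX replicate 1 (adjusted p = 0.0525 and 0.148) or 2 (0.0745 and 0.0763) and with quantile normalization (0.0508 and 0.0656). Nrp1 was also lost without DMSO replicate 1 (0.1005), and Tnfrsf18 without DMSO replicate 2 (0.260). Of 10 coinhibitory receptors 3 fell, Btla at -1.70 (2 adjusted over the list alone; median -0.54, adjusted p = 0.331). Of 15 naive and memory genes 6 rose and 2 fell (6 and 4 adjusted over the list alone), Klf3 at 3.23, Klf2 at 3.15 and Bcl6 from 21.3 ± 3.19 to 138 ± 23.9 RPM (2.66; median 0.96, adjusted p = 0.132). Of 26 early T cell receptor response genes 8 rose and 8 fell (8 and 10 adjusted over the list alone), Fosb at 5.84 and Cd69 at -2.76 (median -0.04, mean 0.34, camera direction up, adjusted p = 0.640). Of 23 interferon-stimulated genes 4 rose and 2 fell (4 and 1 adjusted over the list alone), Rsad2 at 2.07 (median 0.65, adjusted p = 0.276). Of the naive and memory genes 1 fell without DMSO replicate 1, 0 without DMSO replicate 2 and 4 without CPX replicate 2. Of the interferon-stimulated genes 1 rose without DMSO replicate 1, and 0 fell without either DMSO library.

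Genes that build ribosomes fell together with CPX. Of 28 ribosome biogenesis genes 25 fell and 0 rose (26 and 0 adjusted over the list alone), with Polr1b at -4.91, Rrp1b at -3.05, Bop1 at -2.58 and Nop56 at -2.29 (median -1.59, camera, adjusted p = 2.28e-07; adjusted p = 0.784 with an estimated correlation). The 46 ribosomal protein genes were called higher as a list (median 0.41, camera, adjusted p = 3.69e-04; adjusted p = 0.784 with an estimated correlation), but 5 members rose on their own, 0 adjusted over the list alone, and 0 fell. Without DMSO replicate 1 or 2, 0 of them rose, without CPX replicate 1, 1 rose, and without CPX replicate 2, 8 rose. Without DMSO replicate 2 that list's adjusted p was 0.0629. Of 23 PCBP and hnRNP genes 10 fell and 1 rose (10 and 1 adjusted over the list alone), Hnrnpr at -3.28 and Syncrip at -2.62 (median -0.69, camera, adjusted p = 0.0506). With replicates paired by number the list was called (adjusted p = 0.0252; adjusted p = 0.708 with an estimated correlation). Of 24 regulators of cytokine mRNA stability 7 fell and 3 rose (7 and 3 adjusted over the list alone), with Zfp36, which encodes a protein that destabilizes cytokine mRNAs, at 3.73 (median -0.65, adjusted p = 0.353). Without DMSO replicate 1, 15 ribosome biogenesis, 6 PCBP and hnRNP and 3 stability genes fell. Without DMSO replicate 2, 5 PCBP and hnRNP and 4 stability genes fell, and without CPX replicate 2, 11 stability genes fell.

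ATF4 and HIF target genes were called up as lists, although 13 of 26 and 18 of 31 members did not pass. Of 26 ATF4 target genes, which respond to amino acid shortage and other stresses, 12 rose and 1 fell (12 and 1 adjusted over the list alone), with Trib3 at 4.53, Vldlr at 4.18 and Ddit3, which encodes the transcription factor CHOP, from 9.24 ± 1.41 to 177 ± 42.9 RPM (median 0.76, camera, adjusted p = 7.21e-04; adjusted p = 0.757 with an estimated correlation). Of 31 HIF target genes 11 rose and 2 fell (12 and 2 adjusted over the list alone), with the growth factor Vegfa from 46.5 ± 5.22 to 258 ± 25.9 RPM, P4ha2 at 2.82 and Car12 at -3.92 (median 1.04, camera, adjusted p = 0.00403; adjusted p = 0.784 with an estimated correlation). The HIF call was lost without CPX replicate 2 (adjusted p = 0.0639). Of 17 NRF2 genes 7 rose and 2 fell (7 and 2 adjusted over the list alone), Me1 at 3.91 and Txnrd1 at 2.43 (median 0.97, camera, adjusted p = 0.0652). Of 19 cholesterol synthesis genes 6 rose and 0 fell (5 and 0 adjusted over the list alone), Cyp51 at 2.43 (median 0.51, camera, adjusted p = 0.0559). Of 18 glycolysis enzymes 4 rose and 1 fell (4 and 1 adjusted over the list alone), Slc2a3 at 2.36, Eno2 at 2.35 and Hk2 at -2.23 (median 0.56, camera, adjusted p = 0.105). Of 19 unfolded protein response genes 7 fell and 2 rose (9 and 3 adjusted over the list alone), Hyou1 at -2.32 and Pdia4 at -2.31 (median -0.53, camera, adjusted p = 0.0959). With replicates paired by number, camera called the NRF2 (adjusted p = 0.0390), cholesterol synthesis (0.0377) and glycolysis (0.0488) lists. None of the 3 held (adjusted p = 0.740, 0.792 and 0.708 with an estimated correlation). Without CPX replicate 1, 17 HIF targets and 2 cholesterol genes rose, and without CPX replicate 2, 7 HIF targets and 2 glycolysis enzymes rose. Without DMSO replicate 1, 2 glycolysis and 2 cholesterol genes rose, and without DMSO replicate 2, 7 glycolysis enzymes rose and 4 unfolded protein response genes fell.

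Nuclear respiratory chain and TCA cycle genes were called down as lists with CPX, although 19 of 35 and 9 of 21 members did not pass. Of 35 nuclear respiratory chain genes 16 fell and 0 rose (16 and 0 adjusted over the list alone), with cytochrome c1 (Cyc1) from 118 ± 7.38 to 16.0 ± 3.49 RPM and Ndufs7 at -2.11 (median -0.60, camera, adjusted p = 0.00214; adjusted p = 0.757 with an estimated correlation). Of 21 TCA cycle enzymes 10 fell and 2 rose (11 and 2 adjusted over the list alone), Idh3a at -2.43 and Fh1 at -1.67 (median -0.95, camera, adjusted p = 0.0204; adjusted p = 0.757 with an estimated correlation). The TCA call was lost without CPX replicate 2 (adjusted p = 0.0647) and with a filter of 5 RPM (adjusted p = 0.0511). Of 10 mitochondrially encoded genes 1 fell, mt-Nd5 at -1.35 (1 adjusted over the list alone; median -0.12, camera, adjusted p = 0.512). Of 21 iron-sulfur cluster assembly genes 9 fell and 2 rose (11 and 2 adjusted over the list alone), Lyrm4 at -1.99 and Glrx5 at -1.92 (median -0.70, camera, adjusted p = 0.0641). Of 13 heme synthesis genes 6 fell and 1, Slc25a38 at 1.73, rose (7 and 3 adjusted over the list alone), Cpox at -2.31 (median -1.07, camera, adjusted p = 0.341). Of 17 iron handling genes 8 fell, Aco1 at -1.90, and 3 rose, Hmox1 and both ferritin genes (9 and 4 adjusted over the list alone; median -1.02, camera, adjusted p = 0.640), with Slc11a2 at -0.18 (0.675). Of 28 iron-dependent dioxygenases 8 rose and 1 fell (8 and 1 adjusted over the list alone), Kdm5a at 1.88 and Tet2 at 1.62 (median 0.15, camera, adjusted p = 0.163). Without DMSO replicate 1, 5 respiratory chain, 2 iron-sulfur cluster, 3 heme synthesis and 4 iron handling genes fell. Without DMSO replicate 2, 6 respiratory chain, 5 TCA cycle, 2 iron-sulfur cluster, 1 heme synthesis and 3 iron handling genes fell. Without CPX replicate 2, 7 dioxygenases fell.

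Cell cycle lists were not called with CPX, except mitosis genes with replicates paired by number (camera, adjusted p = 0.0406; adjusted p = 0.792 with an estimated correlation). Of 28 mitosis genes 9 fell and 0 rose (9 and 0 adjusted over the list alone), Ccnb1 at -2.94 and Cdk1 at -2.84 (median -0.50, camera, adjusted p = 0.0667). Of 32 DNA replication genes 10 fell and 1 rose (8 and 1 adjusted over the list alone), E2f8 at -2.21 and Mcm2 at -1.64 (median -0.64, camera, adjusted p = 0.0610). Of 7 histone genes 2 rose, Hist1h2bc at 3.08 (2 adjusted over the list alone; median 0.47, camera, adjusted p = 0.341). Only these 7 of the 22 listed histone genes reached the filter in this polyA RNA, against 21 in the total RNA of the knockdown experiment. The histone medians of the 2 experiments therefore cover different members and cannot be set against each other. Of 24 p53 target genes 9 rose and 6 fell (9 and 7 adjusted over the list alone), Gadd45a at 2.43 and Plk2 at -3.34 (median -0.11, mean 0.13, camera direction up, adjusted p = 0.614). Of 25 apoptosis regulators 5 rose and 8 fell (5 and 11 adjusted over the list alone), the p53-induced death gene Bbc3 at 2.90 and the survival gene Bcl2l1 at -3.86 (median -0.49, camera, adjusted p = 0.640). Without DMSO replicate 1, 6 DNA replication genes and 2 apoptosis regulators fell, and 5 p53 targets and 2 apoptosis regulators rose. Without DMSO replicate 2, 4 mitosis, 5 DNA replication, 3 p53 and 3 apoptosis genes fell. Without either DMSO library or CPX replicate 1, 1 histone gene rose.

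Markers of macrophages and monocytes were higher with CPX, from very low levels. Of 5 measured, 4 rose and 0 fell (4 and 1 adjusted over the list alone): Itgam went from 1.63 ± 0.0789 to 37.5 ± 17.0 RPM, Cd68 from 2.04 ± 1.38 to 14.6 ± 0.785 RPM, and Emr1 from 0.0509 and 0 to 3.75 and 5.46 RPM (median 3.26, camera, adjusted p = 0.0342; adjusted p = 0.757 with an estimated correlation, and 0.0514 with median ratio scaling). Of 6 dendritic cell markers 3 rose and 1 fell (5 and 1 adjusted over the list alone), Itgax at 3.35 and H2-Ab1 at 2.19 (median 1.44, camera, adjusted p = 0.0943). Of 6 cytotoxic and NK cell genes 1 rose, Fcgr3 at 2.30 (lost with quantile normalization, 0.0579; 1 adjusted over the list alone; median 0.06, camera, adjusted p = 0.640). In lists too short to test, 2 of 4 CD8 T cell markers fell (Crtam -3.57), 2 of 3 B cell markers rose, 2 of 4 fibroblast or packaging cell markers rose (Col1a1 2.35), the 1 neutrophil marker rose (Mpo, 0.0254 ± 0.0360 to 6.27 ± 1.30 RPM) and the 1 erythroid marker fell (Car2 -2.68). Without CPX replicate 1 or 2, 2 macrophage and monocyte markers and 0 neutrophil markers rose, and a gene had to reach 1 RPM in 2 of the libraries left to be tested. Whichever library was left out, 0 B cell markers rose and 1 CD8 T cell marker fell. Without CPX replicate 1, 0 cytotoxic and NK cell genes and 0 fibroblast or packaging cell markers rose, and 1 of the latter rose without DMSO replicate 1 or CPX replicate 2.

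**Figure D3:**
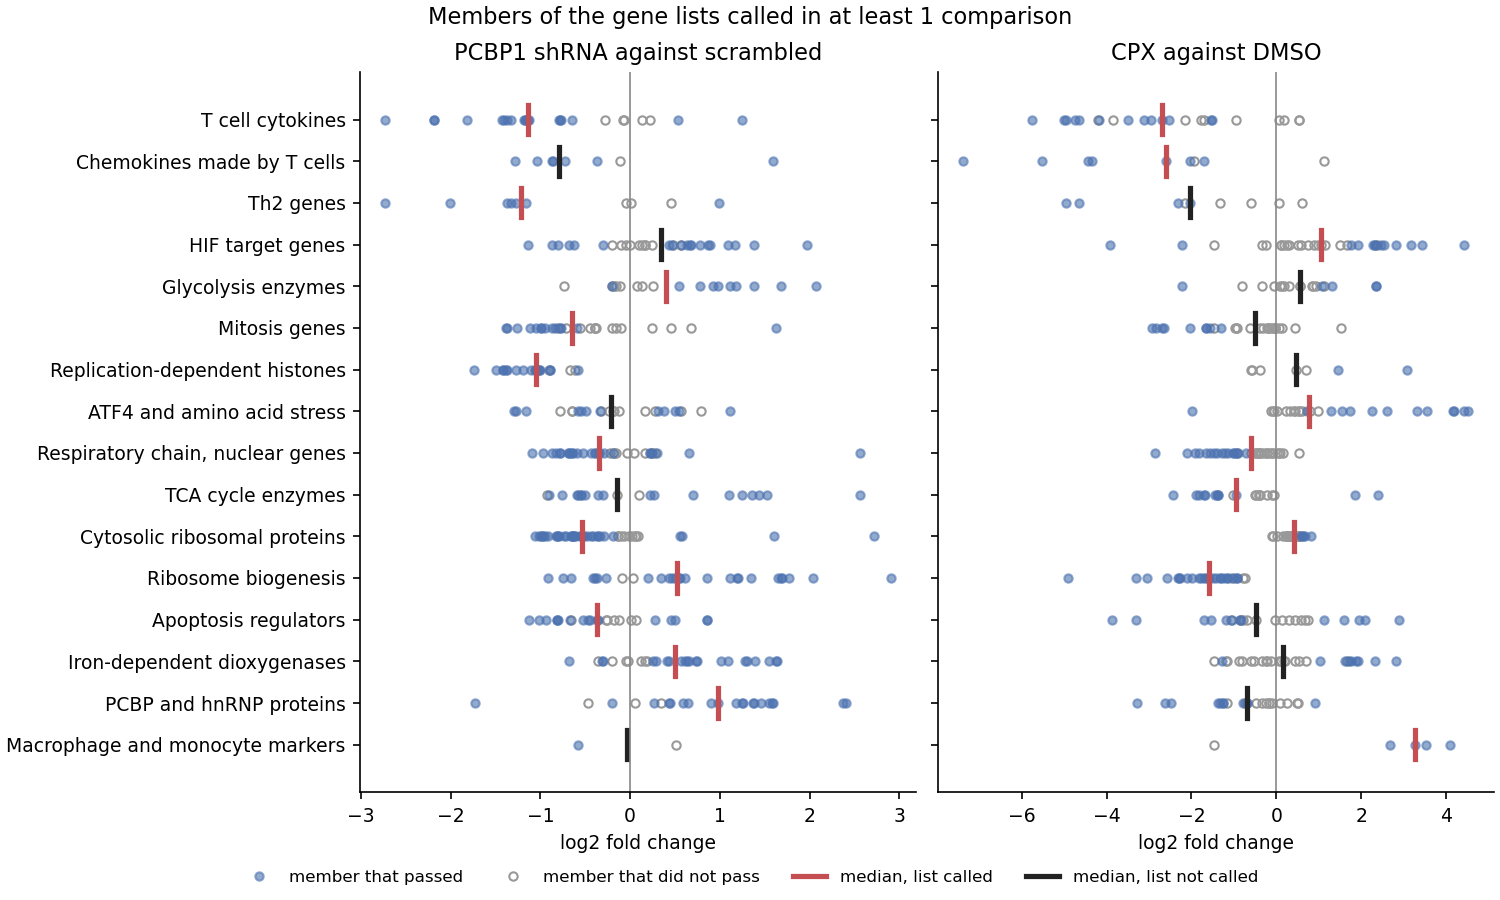
Log2 fold change of each measured member (points, filled where the gene passed) and the median (bars, red where camera called the list) of the gene lists called in at least 1 comparison, knockdown on the left and CPX on the right. Ribosome biogenesis has a median of 0.52 after the knockdown and -1.59 with CPX, ribosomal proteins -0.54 and 0.41, and T cell cytokines -1.14 and -2.70. Replication-dependent histones have 21 members measured after the knockdown and 7 with CPX.

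Set side by side, the Pcbp1 hairpin and CPX did not change the same genes by the same amounts. Across 10430 genes tested in both, the log2 fold changes were uncorrelated (Pearson -0.0225, Spearman -0.0224, across genes, which are not independent replicates). Called in both were 2609 genes, where independent lists would share 2581 (odds ratio 1.05, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.334, 5 overlaps tested), 1235 of them in the same direction. Genes that rose after the knockdown and fell with CPX were in excess, 1068 against 895 expected (odds ratio 1.46, Fisher's exact test, p = 6.18e-16, adjusted p = 3.09e-15). Genes that fell after the knockdown and rose with CPX were fewer than expected, 306 against 424 (0.612, Fisher's exact test, p = 8.91e-14, adjusted p = 2.23e-13). Shared rises (467 against 496, odds ratio 0.902, Fisher's exact test, adjusted p = 0.146) and shared falls (768 against 765, 1.01, adjusted p = 0.901) did not differ from chance in this fit. Without a filter they did, with an odds ratio of 0.628 for shared rises and 1.37 for shared falls. Fisher's test treats genes as independent, which they are not. With length and GC content taken out, the deficit of genes that fell after the knockdown and rose with CPX was lost (odds ratio 0.903, Fisher's exact test, p = 0.120), and shared rises were fewer than expected (0.746, Fisher's exact test, p = 5.83e-06).

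The genes that fell in both, with the knockdown value before the CPX value, included Csf2 (-2.19 and -4.17), Ccr8 (-2.00 and -2.03), Pdzk1ip1 (-1.64 and -4.68), Dhrs11 (-1.59 and -1.76) and Galk1 (-1.51 and -3.30). For Csf2 the difference between the effects was 2.09 and did not pass (limma, adjusted p = 0.280). Genes that rose in both included Rhbdl3 (2.00 and 2.51), Pdcd4 (1.95 and 3.08), an inhibitor of translation, Aplp2 (1.95 and 2.03), Laptm5 (1.89 and 1.72) and Rara (1.74 and 2.30), a retinoic acid receptor. Genes that rose after the knockdown and fell with CPX included Srm (2.58 and -3.32), Dpagt1 (2.31 and -3.62), Nefh (2.25 and -2.20), Mpzl2 (2.04 and -2.64) and Elp3 (2.04 and -2.01). The opposite pattern was seen in Areg (-2.01 and 1.37), Crem (-1.58 and 3.62), Serpinb6a (-1.41 and 1.45) and Glipr1 (-1.32 and 1.86). Leaving out 1 library ended the CPX calls of Csf2 (without CPX replicate 1, adjusted p = 0.0598, or 2, 0.162), Ccr8 (without DMSO replicate 1, adjusted p = 0.0607, or 2, 0.0716), Mpzl2 (without DMSO replicate 1, 0.132, or CPX replicate 1, 0.0695, or 2, 0.171) and Serpinb6a (without DMSO replicate 1, 0.0839, or 2, 0.144). The Ccr8 and Mpzl2 calls were also lost with median ratio scaling (0.0558 and 0.0534), quantile normalization (0.0601 and 0.0702) and no filter (0.0797 and 0.0804). The Csf2 call was lost with quantile normalization (0.0560) and no filter (0.0718). Leaving out 1 library also ended those of Dhrs11 (without DMSO replicate 1, 0.0756), Areg (without DMSO replicate 2, 0.218, or CPX replicate 2, 0.0722) and Glipr1 (without DMSO replicate 1, 0.0611, or CPX replicate 2, 0.0757).

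Tested directly, with the knockdown effect minus the CPX effect, 5346 of 10430 genes differed (limma), 3671 with a positive and 1675 with a negative difference (3204 and 1365 by at least 2-fold). The median difference was 0.40, so the split depends on the scaling: median ratio scaling gave 2627 positive and 2618 negative, and quantile normalization 2784 and 2602. The largest positive differences were in Polr1b (6.21), Ccl1, Srm (5.99), Dpagt1 (5.94), an enzyme of N-glycosylation, and Myc (5.84). The largest negative ones were in Hspa1b (-11.39), Elmod3 (-6.76), Spp1 (-5.84), Soat2 (-5.79) and Trib3 (-5.57). By list, 25 of 28 ribosome biogenesis genes differed positively and 0 negatively (median 2.36), as did 17 and 1 of 23 PCBP and hnRNP genes (1.73), 14 and 2 of 21 TCA cycle enzymes (1.15) and 12 and 0 of 23 cytokines (2.06). Of 46 ribosomal protein genes 2 differed positively and 29 negatively (-0.82), and of 24 ATF4 target genes 2 and 11. These list medians carry no test of their own.

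**Figure D4:**
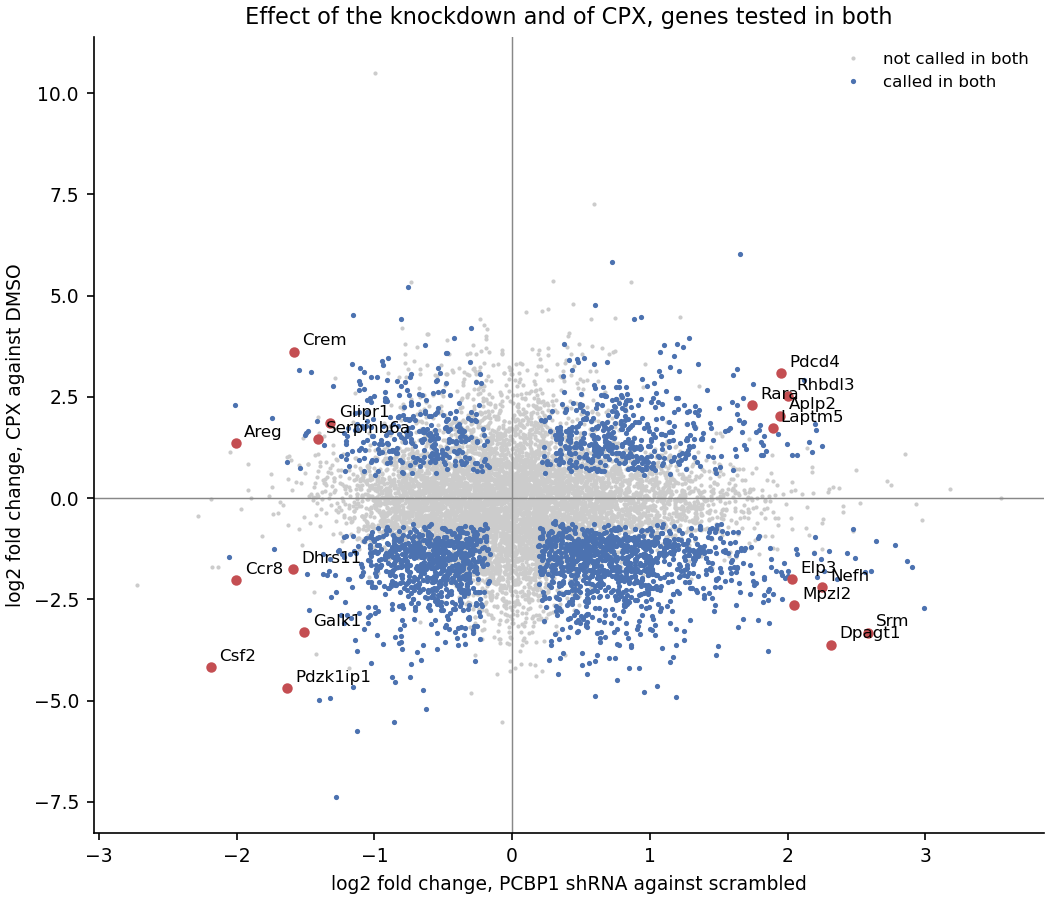
Log2 fold change after the knockdown (horizontal) and with CPX (vertical) of the 10430 genes tested in both (points), coloured where called in both, with the genes named for each pair of directions labelled. The points show no common slope (Pearson -0.0225), and the lower right part, genes that rose after the knockdown and fell with CPX, holds 1068 of the 2609 genes called in both.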

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

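Alternatives to the processing were set before the data were examined, with 4 exceptions. The correction for GC content and length in both forms, the count tests on the deposited CPX numbers, the use of correctly labelled lines alone and the replicate block with an estimated correlation were chosen after the result was seen. Of the values of named genes under alternatives other than leaving out a library, 2184 after the knockdown and 2192 with CPX kept their direction and side of the threshold, 94 and 48 lost the call, 13 and 12 gained it, and 5 and 0 changed direction. For the genes named for the difference all 81 kept theirs. In the fits without 1 library, where a lone library is assumed to vary like the other groups, 654 and 561 values kept direction and call, and 19 and 62 lost the call. The knockdown called 2759 to 7348 genes over all settings, CPX 2298 to 7041 and the difference 2348 to 6720. The excess of genes that rose after the knockdown and fell with CPX kept an odds ratio above 1 in every setting run. Its size depended on the filter, with an odds ratio of 2.16 without a filter, 1.46 in the main fit and 1.25 with a filter of 5 RPM. With the replicate block, a paired fit by replicate number, 7348, 5651 and 5362 genes were called. Under 1 dispersion per experiment and few changed genes, a simulated 2-fold change was recovered for 7.46% with CPX, against 98.5% in the knockdown. Between the real replicates 481 (DMSO) and 1538 (CPX) genes differed over 2-fold, against 47 and 45 in the knockdown experiment.

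In 1 fit of all 8 libraries the knockdown count was 2759, genes called in both numbered 1664, and the odds ratio for falling after the knockdown and rising with CPX was 0.862. With correctly labelled lines alone, which tests fewer genes (5506, 5206 and 4653), the counts were 2804, 2298 and 2348, with 1060 called in both. There were 6 knockdown and 3 CPX lists called, a correlation of -0.0441 and an odds ratio of 0.791 for falling in both, reversed from 1.01. The correlation was -0.0412 with a pseudocount of 2, -0.00121 without a filter, -0.0112 with a filter of 5 RPM and -0.00721 with quantile normalization. It was -0.0683 with GC content and length taken out (-0.0684 without centring). The odds ratio for rising in both was 0.628 without a filter, 0.867 without a variance trend, 0.867 with the replicate block, and 0.871 with DESeq2. It was 0.885 with edgeR on the deposited numbers and 0.746 with GC content and length taken out (0.683 without centring). For falling in both it was 1.37 without a filter. Without a filter both rising and falling in both departed from chance (Fisher's exact test, adjusted p under 0.05). For falling after the knockdown and rising with CPX it was 0.903 with GC content and length taken out (0.918 without centring). With an estimated correlation 0 lists were called in either comparison, also with the replicate block. That form of camera has little power with 2 libraries per group, and still less with the block. CPX lists called numbered 15 without a filter and 16 with the replicate block. After the knockdown mt-Co1 was at 0 with quantile normalization and at 0.0807 with GC content and length taken out. Without centring Hyou1 was at -0.0613, Slc11a2 at -0.0819 and Tbx21 at -0.0247. In 1 fit of all 8 libraries both experiments share 1 estimate of the spread, as in the test of the difference. The CPX and DMSO replicates differed more than those of the knockdown, so the knockdown was set there against a wider spread. CPX calls rose to 7041 in that fit. For the knockdown that fit also used limma without TMM scaling in place of edgeR, and limma on the knockdown libraries alone called 6505 genes. For the other shifts, except for the smaller number of genes tested, the cause was not tested.

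Leaving out 1 library gave 2535 (without DMSO replicate 1) to 5512 (without CPX replicate 2) CPX calls, correlations of -0.0434 to -0.0121, and 1172 (without DMSO replicate 1) to 3338 genes called in both, with 1294 without DMSO replicate 2. It gave odds ratios of 0.772 (without DMSO replicate 2) to 1.15 (reversed, without CPX replicate 1) for rising in both and 0.892 to 1.11 (without CPX replicate 2) for falling in both, and 5 (without CPX replicate 2) to 16 (without DMSO replicate 1) CPX lists. Planned tests on recovered whole reads with edgeR and DESeq2 were not run for CPX or for the difference, since those reads could not be recovered.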

Other observations

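The 5 gene lists of the first 2 paragraphs, the test of myeloid transcripts and the centring of the correction for GC content and length were chosen after the result was seen. The patterns below came from the comparisons above, and their outcomes, apart from that of the myeloid test, were predicted before the tests were run. No outcome was predicted for the 5 lists. They were tested on the same libraries that had been seen when they were chosen, and adjusted over these 5 lists alone in each comparison. Their camera p-values are therefore descriptive and no independent test. With CPX, heat shock genes, which encode chaperones, rose as a group. Of 22 measured, 18 rose and 3 fell (median log2 fold change 1.85, camera, adjusted p = 5.97e-07; adjusted p = 0.0939 with an estimated correlation), among them Hsph1 from 643 ± 44.7 to 4960.4 ± 343 RPM (SD, n = 2 each), Dnajb1 at 2.88 and Hspa8 at 1.55. Genes of purine and pyrimidine synthesis, which make nucleotides, fell: 14 of 18 fell and 0 rose (median -1.79, camera, adjusted p = 9.01e-06; adjusted p = 0.0939 with an estimated correlation), with Cad, the first enzyme of pyrimidine synthesis, from 473 ± 6.22 to 15.8 ± 4.43 RPM, Pfas at -4.19 and Dhodh at -3.82. Of 35 lysosomal genes 20 rose and 4 fell (median 0.94, camera, adjusted p = 6.17e-04; adjusted p = 0.389 with an estimated correlation), with the autophagy receptor Sqstm1 from 216 ± 8.04 to 1764 ± 241 RPM, Ctsd at 3.06 and Gusb at -3.79. Of 31 proteasome subunits 8 fell and 0 rose (median -0.34, camera, adjusted p = 0.0486; adjusted p = 0.552 with an estimated correlation), and of 20 tRNA synthetases 4 rose and 8 fell (median -0.22, camera, adjusted p = 0.571).

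After the knockdown, 14 of 20 tRNA synthetases rose and 1 fell (median 0.38, camera, adjusted p = 5.13e-04; adjusted p = 0.344 with an estimated correlation), with Kars from 86.0 ± 5.34 to 363 ± 13.6 RPM (SD, n = 2 each), Farsa at 1.98 and Dars at -0.97. Of 31 proteasome subunits 18 fell and 7 rose (median -0.41, camera, adjusted p = 0.0157; adjusted p = 0.538 with an estimated correlation), Psmc6 at -1.13 and Psmd12 at 1.81. Heat shock genes (10 rose and 6 fell of 19, camera, adjusted p = 0.413), nucleotide synthesis genes (10 rose and 4 fell of 18, adjusted p = 0.0744) and lysosomal genes (13 rose and 9 fell of 33, adjusted p = 0.649) were not called.

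The knockdown's lists lie along a trend with transcript length and GC content, which splines of both fit with an R squared of 0.223 across genes. With the trend taken out, the cytokine median went from -1.14 to -0.59 (SD of members 0.712, camera, adjusted p = 8.94e-04), ribosomal proteins from -0.54 to -0.26 (SD 0.698, adjusted p = 0.0194), ribosome biogenesis from 0.52 to 0.28 (SD 0.865, adjusted p = 0.00107) and PCBP and hnRNP genes from 0.98 to 1.19 (SD 0.926, adjusted p = 3.27e-06). The calls that stayed argue against length and GC content, as measured on 1 reference transcript per gene, as the whole cause. The correction was not complete: a weak trend with length remained (rho 0.0478, median -0.10 over the shortest transcripts). A part of the trend that these measures miss is not excluded. Ribosomal proteins, though, fell below the size set beforehand for that cause (0.27). None of these calls held with an estimated correlation (camera, lowest adjusted p = 0.569), a form of the test with little power here. Of 6370 called genes that could be looked up, 4521 kept call and direction, and 23 were called in the opposite direction. Whether the trend comes from the RNA libraries or from a response of short transcripts to the loss of PCBP1 was not tested and stays open. Over genes tested in both experiments, the Pcbp1 hairpin mean correlated with the DMSO mean at 0.886, and the scrambled mean at 0.826 (Pearson, log2 scale). The scrambled libraries thus stood further from the DMSO cells. Since RNA selection differs between the experiments, these values cannot say which hairpin group departs.

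Of 28 ribosome biogenesis genes 17 were called as risen after the knockdown and fallen with CPX, while 7 fell after the knockdown. Neither list call held with an estimated correlation (camera, adjusted p = 0.541 for the knockdown and 0.784 for CPX). Scaling of the libraries would move all genes alike, and the list's median difference between the effects was 2.36 (SD 1.38) against 0.40 over all genes. Of its members 25 differed positively and 0 negatively. These values restate the pattern that had led to the question, so they are no separate test of scaling. The excess of genes that rose after the knockdown and fell with CPX was not removed by the correction for length and GC content. Its odds ratio was 1.59 afterwards (925 genes against 734 expected, Fisher's exact test, p = 3.79e-21). The correction did end the deficit of genes that fell after the knockdown and rose with CPX (0.903, Fisher's exact test, p = 0.120), and shared rises became fewer than expected (0.746, Fisher's exact test, p = 5.83e-06). The RNA selection, total RNA without ribosomal RNA against polyA RNA, differs between the experiments and was not tested, so its part in the contrast stays open.

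The rise of macrophage and monocyte markers with CPX (Itgam, Emr1, Cd68 among them) might come from RNA of myeloid cells in the CPX libraries. Against it, 18 abundant myeloid transcripts, among them Lyz2, Tyrobp, C1qa, Csf1r and S100a8, had a median mean of 1.22 normalized counts in the authors' deposited table, with 17 below 10 and 4 at 0. The highest was Lst1 at 12.2, against 88.5 for Emr1, 319 for Cd68 and 757 for Itgam. These means pool the DMSO and CPX libraries. Expression of these genes in the T cells themselves stays open as a hypothesis, and no sort of the cells is given in the sources used here.

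PCBP1 binds C-rich RNA, so as a hypothesis transcripts with C-rich 3′ untranslated regions might fall when it is lost. Across 10024 of 10196 protein-coding genes (98.3%), the partial Spearman correlation of the knockdown log2 fold change with the percent C of the 3′ untranslated region, given GC content and length, was 0.00156, where the hypothesis needed -0.1 or lower. Without those terms the correlation was 0.233, in the direction opposite to the hypothesis. The Csf2 region holds 17.5% C, below the median of 21.7%. The test covers the composition of the whole region and leaves open single binding sites and changes in translation.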
